A study of Mus musculus with 12 samples.

How the data were processed

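The series holds ATAC-seq of LT-HSC and MPP from male mice, 12 libraries in 4 groups of 3. WT libraries came from mice with a floxed Phf6 allele and no Cre (Phf6f/Y Rosa26+/+), and KO libraries from mice with the deleted allele and a tamoxifen-activated Cre at Rosa26 (Phf6−/Y Rosa26+/Cre-ERT2). Per the labels, nuclei of 20000 sorted LT-HSC came from separate mice of each genotype 8 weeks after tamoxifen, were tagmented with Nextera Tn5 and sequenced as 1 pool with paired 75 nt reads on a NextSeq 500. Replicates are treated as separate animals on that wording alone, which is given for LT-HSC. How MPP were prepared, and whether LT-HSC and MPP of the same number share an animal, is not given in the sources used here. Cre-ERT2 is present in every KO and in no WT library, so its own effect cannot be parted from that of Phf6.

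The deposited values are raw counts of reads per accessible region, in 1 table of a union set of regions for all libraries, and the counts carry no normalization by the authors. The submitters' processing notes name cutadapt, Bowtie2, MACS2 2.1.1, featureCounts and DESeq2 1.22.1 and the build GRCm38. The order, settings and filters of these steps, and how the union set was made, are not given in the sources used here. All 12 count columns matched a sample through the labels' descriptions. The table held 188262 regions of 402 to 3503 bp (median 453 bp) covering 93.8 Mb. Total counts ran from 22665988 to 48547234 per library, and the median count per region from 40.0 to 81.0. PCR duplicates and reads outside the regions were not seen in such a table, so signal over background could not be measured directly.

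Regions were placed against RefSeq genes of GRCm38, 21900 protein-coding genes in all. The gene table held no strand, so promoters could not be told from 3' ends. Gene ends, meaning regions within 1 kb of either end of a protein-coding gene (24508 regions), stand in for the planned promoter class, and other regions are gene body or intergenic. A region was assigned to the gene it overlapped or otherwise to the nearest gene body within 100 kb, in place of the planned nearest start site. This assigned 172530 regions (91.6%) and gave 18622 genes at least 1 region. Assignment by distance does not show that a region acts on that gene. No genome sequence was used here, so the planned transcription factor motif sets and the GC and length offset were not run.

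Comparisons were fitted with edgeR 4.0.16 in R 4.3.3 on all 12 libraries, in a model with 1 mean per group, TMM factors and filterByExpr, which left out 1889 regions and kept 186373. The quasi-likelihood F test (2-sided) gave p-values for KO against WT in LT-HSC and in MPP, for the interaction, and for MPP against LT-HSC in WT and in KO. They were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Log2 CPM used a prior count of 2, the biological coefficient of variation was 8.24%, and log2 fold changes are of KO over WT or MPP over LT-HSC. Pairs of replicates had r from 0.971 to 0.982 on log2 CPM and a chi-square per degree of freedom from 1.56 to 3.18. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so no such test was used for single values.

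The comparisons, tests, alternatives, lists and naming rule were chosen before the data were examined, apart from those named here and in the closing section as chosen after. Named genes were all regions at Phf6, and per comparison the 8 higher and 8 lower called regions with the largest log2 fold change among those above the median level, with a gene symbol that is not a predicted model and no overlap of libraries. For each list that passed or held called regions, up to 4 members with the lowest p were added. For the interaction 4 regions per direction were named, or the 3 lowest p where none passed. Leaving out a library ended the call of 39 of 78 named regions called in LT-HSC and of 20 of 79 in MPP, and the gene-end covariate ended 48 and 27 of these. The text prefers regions whose calls were kept when a library was left out.

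The 17 lists (266 genes) were HSC identity, MPP and lymphoid priming, myeloid, megakaryocyte and erythroid, T cell, B cell, NK cell, macrophage and endothelial, TNF and NF-kB, interferon, AP-1 and immediate early, cell cycle, ribosome biogenesis, HSC aging, Notch and T-ALL, NuRD complex and Hoxa cluster. The first 8 also serve as markers of other cell types that a sort could hold. All regions of a list's genes were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 17 lists, and with an estimated correlation. Several lists share genes of the sorted cells themselves, and regions of 1 gene are not independent. A heat shock list was added after the data were examined.

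Alternatives were DESeq2 1.42.0, limma-voom, RLE, total-count and loess scaling, no filter, at least 1 CPM in 3 libraries, the compared groups alone, autosomes alone, an adjusted p under 0.01, replicate number as a block, and leaving out each library. Lists were also run with fry, on gene-end or other regions alone, and with tighter assignment. Ranges over alternatives given for a list leave out fry. After the data were examined 4 more were added: without regions on Y, unplaced scaffolds or above 100 CPM, with each library's gene-end share as a covariate, away from gene ends alone, and without WT library 2 of both populations. The gene-end share comes from the tested counts and differed between groups, so that covariate can take up part of the group differences. No scaling moved the median of all regions by as much as 0.1 on the log2 scale.

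The pipeline was tested on simulated data made from these counts. Of regions simulated as changed, 2-fold changes were recovered at 59.7% in LT-HSC and 67.2% in MPP, and 4-fold changes at 89.4% and 95.5%. Changes of 1.5-fold were recovered at 26.9% and 17.9%, with 10 and 6 false calls. In each comparison 67 regions were changed 1.5-fold, 67 2-fold and 66 4-fold, far fewer than the real comparisons called. The Benjamini-Hochberg adjustment is stricter when few regions change, so recovery in the real comparisons was not measured. A simulated 1.3-fold rise of the interferon list was called, with 0 of the 16 other lists called by camera. Regions were simulated as independent, so this does not test camera where regions of 1 gene move together. Random sets, figures and tables used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R.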

Results

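Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in 12 libraries from male mice. Long-term haematopoietic stem cells (LT-HSC), which sustain blood formation for life, gave 3 wild-type (WT) and 3 Phf6 knockout (KO) libraries. Multipotent progenitors (MPP), their early descendants, gave another 3 of each genotype. Total counts in accessible regions were 34039249, 34859604 and 33356932 in WT LT-HSC and 37008294, 28576266 and 22665988 in KO LT-HSC. They were 39960758, 48547234 and 28842890 in WT MPP and 26399192, 41086637 and 37580274 in KO MPP. The table held 188262 regions with a median length of 453 bp, and 186373 were tested. Below, a region carries the name of its assigned gene, levels are CPM, counts scaled by library size, with SD and n = 3, and log2 fold changes carry their SE.

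Population was the main difference between the libraries. The first principal component held 80.3% of the variance and parted LT-HSC from MPP, and the second held 5.05% and parted KO from WT in both populations. Gene-end regions took a slightly larger part of the counts in KO LT-HSC, with 39.2% to 39.6% against 37.8% to 38.9% in WT LT-HSC. In MPP the ranges met, at 41.0% to 41.4% in KO and 39.2% to 41.0% in WT.

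**Figure D1:**
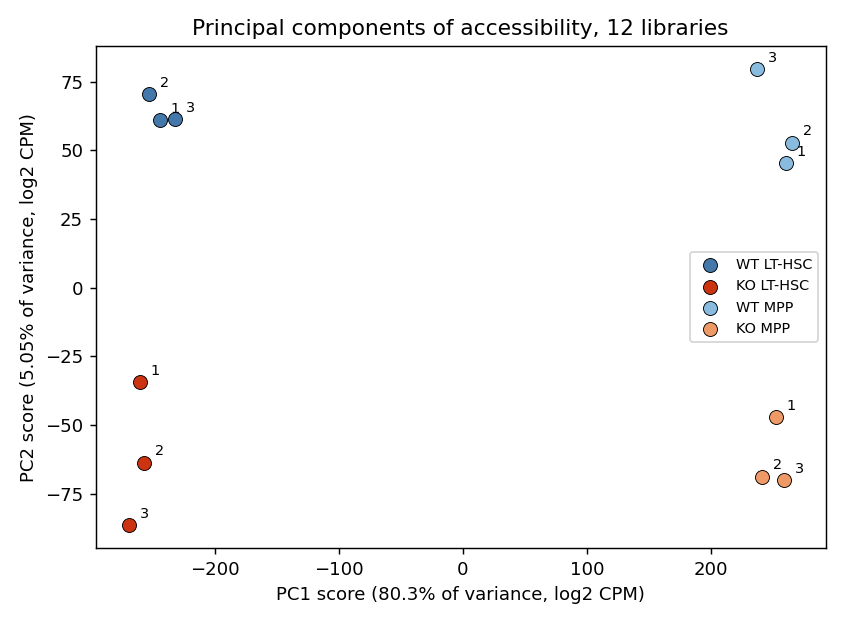
Each point is 1 of the 12 libraries, labelled by its replicate number, placed by its scores on the first (80.3% of variance) and second (5.05%) principal components of log2 CPM, with 1 colour or marker per group. LT-HSC and MPP part along the first component, and KO and WT part along the second in both populations.

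Phf6, the X-linked gene targeted here, encodes a nuclear protein with PHD-like zinc fingers that is mutated in leukaemias. The region at its gene end (GRCm38 chromosome X, 52912011 to 52912448) held 26.6 ± 1.05 CPM in WT and 27.5 ± 1.2 CPM in KO LT-HSC (log2 fold change 0.05 ± 0.07, adjusted p = 0.724). In MPP it held 31.4 ± 0.914 CPM in WT and 28.6 ± 1.02 CPM in KO (log2 fold change -0.14 ± 0.07, adjusted p = 0.195). Of 10 regions assigned to Phf6, the 1 that passed the test in either genotype comparison was higher in KO MPP. That region, in the gene body at 52913820 to 52914221, held 1.45 ± 0.0504 CPM in WT and 2.52 ± 0.162 CPM in KO (log2 fold change 0.79 ± 0.18, adjusted p = 0.00481). With the loess offset the gene-end region in MPP passed as lower (-0.19, adjusted p = 0.0398; range over its alternatives 0.0398 to 0.449). Another of the 10 regions passed as higher in KO MPP under an alternative. Over its alternatives the log2 fold change ran from 0.442 to 0.756 and the adjusted p from 0.0329 to 0.396. These counts do not check the deletion. At the Rosa26 locus, which carries Cre-ERT2 in KO, the strongest region (chromosome 6, 113076354 to 113077033, at Setd5) had log2 fold changes of 0.12 ± 0.06 in LT-HSC (adjusted p = 0.273) and 0.05 ± 0.06 in MPP (adjusted p = 0.676).

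The KO against WT comparison in LT-HSC asked which regions change accessibility in stem cells that lack Phf6, the purpose the series title gives. Regions at chaperone genes of the heat shock response were among the most strongly raised. Accessibility at Hsph1, an HSP110 chaperone (chromosome 5, 149628445 to 149629619, gene body), rose from 0.960 ± 0.855 to 6.61 ± 1.11 CPM, a log2 fold change of 2.77 ± 0.31 (adjusted p = 4.44e-06; 3.75 without WT LT-HSC 3). At Hsp90aa1, the inducible cytosolic HSP90 (chromosome 12, 110686740 to 110687419, intergenic), it rose from 2.88 ± 1.34 to 12.3 ± 3.91 CPM (log2 fold change 2.07 ± 0.23). Regions at the HSP40 co-chaperone genes Dnajb1 and Dnajb4 rose by log2 fold changes of 1.94 ± 0.24 (2.61 without WT LT-HSC 3) and 1.75 ± 0.23 (2.35 with the gene-end share as a covariate). The strongest named loss whose call was kept under every alternative was in the body of Sorcs2, a sortilin-family receptor gene (chromosome 5, 36113695 to 36114140), from 8.75 ± 0.563 to 2.34 ± 0.554 CPM (log2 fold change -1.90 ± 0.15, adjusted p = 1.79e-09). A weak region at Nxpe4 ranked above it (log2 fold change -2.45 to -1.87 over its alternatives). Its call was lost in 7 of 19 alternatives that gave an adjusted p (0.021 to 0.161). Regions at Alkbh5, an RNA demethylase gene, and Ctse, the cathepsin E gene, also fell, with log2 fold changes of -1.47 ± 0.26 and -1.47 ± 0.25. The KO libraries were uneven there. KO LT-HSC 1, 2 and 3 held 0.606, 0.814 and 1.47 CPM at Alkbh5 and 0.633, 0.672 and 1.51 CPM at Ctse. Library 3 was also the highest in KO MPP (1.86 and 1.94 CPM), and the cause was not tested.

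**Figure D2:**
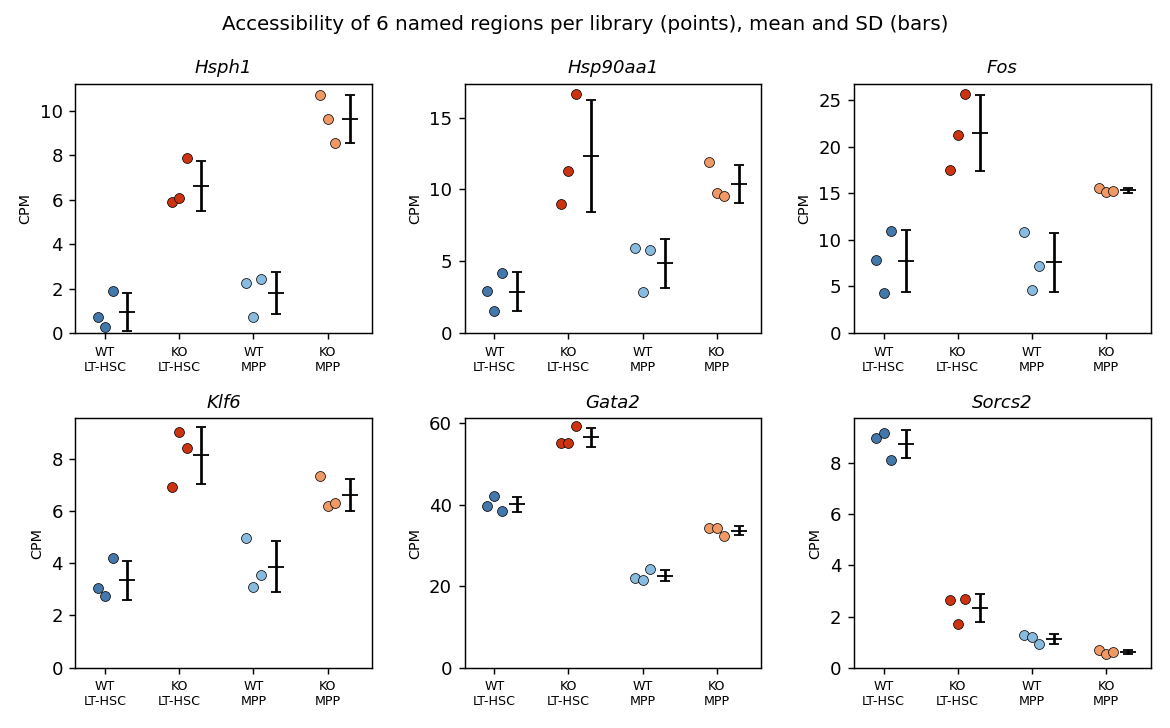
Points are CPM of single libraries, and bars show the mean and SD (n = 3), for regions at Hsph1, Hsp90aa1, Fos, Klf6, Gata2 and Sorcs2 in the 4 groups. Hsph1 rises from 0.960 to 6.61 CPM and Sorcs2 falls from 8.75 to 2.34 CPM between WT and KO LT-HSC.

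The list of AP-1 and immediate early genes, many of them induced within minutes of a stimulus, had the clearest rise in KO LT-HSC. Of all 186373 tested regions 6093 were higher and 2741 lower, and of the list's 319 regions 69 were higher and 1 lower. In the list 19 of 20 genes had a higher region. Adjusted over the list alone, 90 were higher and 3 lower. The list passed the camera test (adjusted p = 2.24e-08), but not with an estimated correlation (adjusted p = 0.101 with an estimated correlation, the highest of its alternatives, whose lowest was 5.21e-14). Klf6 rose from 3.34 ± 0.759 to 8.12 ± 1.09 CPM (log2 fold change 1.27 ± 0.15) and Fos from 7.72 ± 3.34 to 21.5 ± 4.09 CPM (1.47 ± 0.20). Fosb (1.01 ± 0.13) and Egr2 (0.51 ± 0.06) rose as well. The 88 list regions called in either population were lowest in WT library 2 among the LT-HSC libraries, at -0.62 on the log2 scale from the mean of the 6 libraries. The other WT libraries lay at -0.25 and -0.06, and the KO libraries lay between 0.28 and 0.36.

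Some regions at stem cell and signalling genes were also higher in KO LT-HSC. In the HSC identity list 25 of 710 regions were higher and 2 lower, 11 of its 22 genes had no called region, and 17 were higher adjusted over the list alone (adjusted p = 0.00365, but adjusted p = 0.0833 with an estimated correlation). The list's share of higher regions was close to that of all tested regions, 6093 of 186373. Its members Gata2 (40.1 ± 1.87 to 56.5 ± 2.4 CPM, log2 fold change 0.49 ± 0.06), Mecom (5.50 ± 0.468 to 10.1 ± 0.71 CPM, 0.87 ± 0.11) and Erg (0.51 ± 0.08), transcription factors of stem cell maintenance, rose. The TNF and NF-kB list had 23 of 297 regions higher and 3 lower, or 32 and 4 adjusted over the list alone (adjusted p = 0.00365, but adjusted p = 0.101 with an estimated correlation). Nfkb1, an NF-kB subunit gene (log2 fold change 0.55 ± 0.09), Nfkbiz (1.14 ± 0.20) and Tnfaip3, an inhibitor of the pathway (0.45 ± 0.08), rose, while a region at Cebpb fell (-0.47 ± 0.10; with the gene-end share as a covariate its adjusted p was 0.057, the highest of its alternatives, whose lowest was 0.00125). Over their alternatives the adjusted p ran from 0.00132 to 0.0833 for HSC identity and from 0.00132 to 0.147 for TNF and NF-kB, the latter with the loess scaling. HSC identity also missed on gene-end regions alone (adjusted p = 0.0673).

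Interferon response genes, ribosome biogenesis genes and the Hoxa cluster passed the camera test in LT-HSC with fewer regions. The interferon list had 12 of 124 regions higher and 1 lower, or 15 and 3 adjusted over the list alone (adjusted p = 0.00179, but adjusted p = 0.0585 with an estimated correlation, the highest of its alternatives, whose lowest was 0.000801). Ly6e, an interferon-induced surface protein gene (log2 fold change 0.47 ± 0.08), and Ifih1, the RNA sensor MDA5 (0.64 ± 0.13), rose. The ribosome biogenesis list had 5 of 76 regions higher and 2 lower, or 6 and 2 adjusted over the list alone (adjusted p = 0.00272, but adjusted p = 0.0744 with an estimated correlation). Its adjusted p ran from 0.000233 to 0.0796 over the alternatives, the highest being that away from gene ends. The member Polr1a, the largest subunit of RNA polymerase I, rose by 0.43 ± 0.08. With the gene-end share as a covariate the calls of Ly6e, Ifih1 and Polr1a ended (adjusted p = 0.0645, 0.0606 and 0.0762), each the highest over its alternatives, whose lowest were 0.000166, 0.00186 and 9.14e-05.

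The Hoxa cluster of homeobox genes, which act in stem cell self-renewal, had 4 of 54 regions higher in KO LT-HSC and 6 adjusted over the list alone. The list passed the camera test (adjusted p = 0.00179), but not with an estimated correlation (adjusted p = 0.258 with an estimated correlation, the highest of its alternatives, whose lowest was 0.000185). The regions lay at Hoxa5 (log2 fold change 0.41 ± 0.11), Hoxa9 (0.28 ± 0.08), Hoxa10 (0.29 ± 0.08) and Hoxa13 (0.84 ± 0.24). These 4 calls were close to the threshold. Hoxa5 was lost without any 1 library except WT 3 (adjusted p up to 0.0813). Hoxa9 was lost without any 1 of the 6 (up to 0.18), and Hoxa10 and Hoxa13 without any 1 except WT 1 (up to 0.142 and 0.13). Here the library left out was WT 1, WT 2, WT 3, KO 1, KO 2 or KO 3 of LT-HSC. The gene-end covariate ended all 4 calls, and over all alternatives the adjusted p ran from 0.0151 to 0.29, 0.0358 to 0.186, 0.025 to 0.212 and 0.0264 to 0.173.

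The other 11 lists did not pass in LT-HSC. Their adjusted p was 0.139 for cell cycle (13 of 249 regions higher, 5 lower). Cell cycle passed on gene-end regions alone (adjusted p = 0.000801) and with the tighter assignment (adjusted p = 0.00201), in a range over its alternatives from 0.000801 to 0.41. The adjusted p was 0.327 for MPP and lymphoid priming (10 and 1 of 193) and 0.327 for T cell (3 and 6 of 142). It was 0.484 for myeloid (8 and 5 of 216), for megakaryocyte and erythroid (8 and 2 of 134) and for Notch and T-ALL (6 and 1 of 188). B cell (1 higher of 124), HSC aging (13 and 5 of 270) and the NuRD complex (2 and 2 of 156) each had 0.581. NK cell (2 and 2 of 63) and macrophage and endothelial genes (4 and 2 of 143) each had 0.966. The median of the macrophage and endothelial list and the mean of the Notch and T-ALL list had the opposite sign to their test.

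In all, 8834 of 186373 regions passed in LT-HSC, 6093 higher and 2741 lower in KO. Changes of at least 2-fold were mostly losses, with 204 higher and 979 lower. WT and KO libraries did not overlap at 8605 of the called regions and at 24.2% of tested regions, against 10% given by chance. The balance of gains and losses moved with the scaling and the tool. In edgeR 69.0% of the called regions were higher with TMM, 69.4% with RLE, 45.2% with total counts (3214 higher, 3894 lower) and 55.3% with the loess offset. With DESeq2, which gave no adjusted p for 86721 regions, 82.2% were higher. The count fell to 1843 with the gene-end share as a covariate, to 6203 without WT library 2 of both populations, and to 4961, 5291, 4655, 3404 and 4572 without WT 1, WT 2, KO 1, KO 2 and KO 3 of LT-HSC.

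The same comparison in MPP asked how loss of Phf6 changes accessibility in the next population. The chaperone regions were again among the most strongly raised. Hsph1 rose from 1.79 ± 0.943 to 9.61 ± 1.07 CPM (log2 fold change 2.49 ± 0.26, adjusted p = 1.04e-06), and Dnajb1 rose from 1.60 ± 0.672 to 6.28 ± 0.635 CPM (2.01 ± 0.25). The gene end of Egr1, an immediate early transcription factor (chromosome 18, 34864965 to 34865773), rose from 4.45 ± 2.05 to 14.0 ± 2.09 CPM (1.62 ± 0.20, adjusted p = 1.66e-05). Trim37, a ubiquitin ligase gene, gained a region by 1.43 ± 0.18. Sorcs2 fell again, here at 36130036 to 36130852 from 3.35 ± 0.569 to 1.18 ± 0.205 CPM (-1.50 ± 0.18, adjusted p = 6.86e-06). Regions at Frmd4a (-1.25 ± 0.19) and Sdk2 (-1.32 ± 0.25), genes of cell polarity and cell adhesion, fell as well.

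Of all 186373 tested regions 9542 were higher and 6688 lower in KO MPP. In MPP the immediate early list had 57 regions higher and 2 lower, or 71 and 5 adjusted over the list alone (adjusted p = 2.7e-05, but adjusted p = 0.119 with an estimated correlation). Ier5 (log2 fold change 0.50 ± 0.09) and Klf6 (0.77 ± 0.14) were among them. The TNF and NF-kB list had 30 higher and 6 lower, or 35 and 7 adjusted over the list alone (adjusted p = 0.000122, but adjusted p = 0.0645 with an estimated correlation). Its members Cebpb (0.78 ± 0.10), Tnfaip2 (0.59 ± 0.10) and Nfkbiz (0.46 ± 0.08) rose. The Klf6, Cebpb and Nfkbiz regions here were not those named for LT-HSC. The Cebpb region that fell in LT-HSC was lower in KO MPP too (14.11 to 14.99 CPM in WT, 11.19 to 11.6 CPM in KO). The Cebpb region named here was higher in KO LT-HSC too (12.53 to 15.45 CPM in WT, 15.72 to 17.19 CPM in KO). The interferon list had 15 higher and 1 lower, or 21 and 1 adjusted over the list alone (adjusted p = 0.00298, but adjusted p = 0.0645 with an estimated correlation), with the antiviral genes Bst2 (0.43 ± 0.07) and Irf7 (0.42 ± 0.08). These were the highest values over their alternatives, whose lowest were 1.2e-10, 1.16e-05 and 0.000109. The interferon list also missed away from gene ends (adjusted p = 0.0545). The immediate early regions were again lowest in WT library 2, at -0.44 on the log2 scale from the mean of the 6 MPP libraries. The other WT libraries lay at -0.11 and -0.24, and the KO libraries lay between 0.23 and 0.33.

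Some regions at stem cell, Hoxa, cell cycle and megakaryocyte and erythroid genes also rose in KO MPP. The HSC identity list had 64 of 710 regions higher and 9 lower, or 67 and 12 adjusted over the list alone (adjusted p = 0.0143, but adjusted p = 0.119 with an estimated correlation). Gata2 rose from 22.6 ± 1.44 to 33.6 ± 1.17 CPM (log2 fold change 0.58 ± 0.07), and Erg (0.50 ± 0.08) and Procr, the stem cell marker EPCR (0.46 ± 0.07), rose too. In the Hoxa cluster 4 regions were higher, adjusted over the list alone as over all regions (adjusted p = 5.49e-05, but adjusted p = 0.119 with an estimated correlation). They lay at Hoxa5 (0.78 ± 0.12), Hoxa13 (1.25 ± 0.27) and Hoxa11 (0.71 ± 0.19, lost without WT MPP 1 and KO MPP 3, adjusted p = 0.0638 and 0.117, and with the gene-end covariate, in a range from 0.0186 to 0.117). The cell cycle list had 23 of 249 regions higher and 9 lower, or 27 and 9 adjusted over the list alone (adjusted p = 0.00991, but adjusted p = 0.119 with an estimated correlation). Its members Mcm6, a replication helicase subunit (0.70 ± 0.12), and Cdk6 (0.65 ± 0.12) rose.

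The megakaryocyte and erythroid list had 19 of 134 regions higher and 1 lower in KO MPP, or 22 and 1 adjusted over the list alone (adjusted p = 0.0183, but adjusted p = 0.119 with an estimated correlation). Zfpm1, the GATA1 partner FOG1 (log2 fold change 0.81 ± 0.13), and Epor, the erythropoietin receptor (1.07 ± 0.22), rose, while the 1 lower region lay in Vwf (-1.02 ± 0.19). Over the alternatives the adjusted p ran from 0.00141 to 0.119 for HSC identity, from 3.4e-06 to 0.119 for Hoxa, from 3.19e-05 to 0.119 for cell cycle and from 0.00632 to 0.267 for megakaryocyte and erythroid. The last missed without WT MPP 1 (0.0694), without KO MPP 3 (0.0535), with the loess offset (0.055) and on gene-end regions alone (0.267). HSC identity missed without WT MPP 2 (0.0606).

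**Figure D3:**
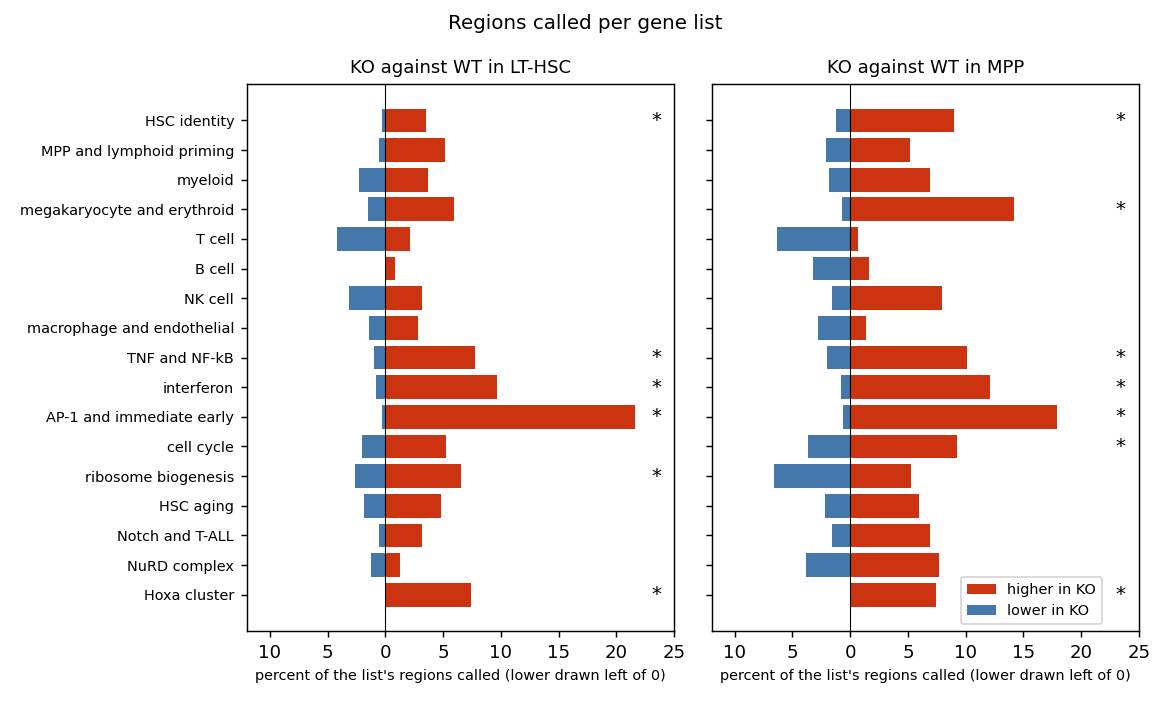
Bars give the percent of each of the 17 lists' tested regions that were higher (right of 0) or lower (left of 0) in KO, for LT-HSC and MPP, and a star marks a camera adjusted p under 0.05 with the preset correlation. Immediate early genes lead in LT-HSC, with 69 of 319 regions higher, and 6 lists in LT-HSC and 7 in MPP carry a star.

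The other 10 lists did not pass in MPP. T cell genes came closest, with 1 region higher and 9 lower of 142 (adjusted p = 0.0531), among them Zap70 (log2 fold change -0.42 ± 0.10) and Tcf7 (-0.30 ± 0.08). The Zap70 call was lost with the gene-end covariate (adjusted p = 0.133) and without WT MPP 2 (0.051), in a range from 0.00505 to 0.133. The Tcf7 call was lost with the covariate (0.0649), without WT MPP 2 (0.0606) and without KO MPP 3 (0.136), in a range from 0.00243 to 0.136. The adjusted p was 0.0916 for Notch and T-ALL (13 regions higher, 3 lower), 0.0991 for MPP and lymphoid priming (10 and 4), 0.254 for the NuRD complex (12 and 6) and 0.261 for B cell (2 and 4). It was 0.426 for HSC aging (16 and 6), 0.565 for NK cell (5 and 1), 0.739 for ribosome biogenesis (4 and 5), 0.892 for macrophage and endothelial (2 and 4) and 0.951 for myeloid (15 and 4), which passed on gene-end regions alone (adjusted p = 0.0253; range 0.0253 to 0.967). Medians of the NK cell (-0.04), myeloid (-0.01) and macrophage and endothelial (0.03) lists had the opposite sign to their test.

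In all, 16230 regions passed in MPP, 9542 higher and 6688 lower in KO, with 449 higher and 1009 lower by at least 2-fold. WT and KO libraries did not overlap at 15512 of them and at 28.0% of tested regions, against 10% given by chance. With TMM 58.8% of the called regions were higher, and with total counts 47.8% (7668 higher, 8383 lower). The count fell to 5614 with the gene-end share as a covariate, to 10653 without WT library 2 of both populations, and to 9743, 6734 and 6435 without WT MPP 2, KO MPP 2 and KO MPP 3.

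Gains in KO lay at gene ends more often than tested regions did. Gene-end regions made up 13.1% of tested regions, 33.0% of those higher in KO LT-HSC (odds ratio 3.45, 95% interval 3.27 to 3.65) and 29.2% of those higher in KO MPP (2.95, 2.82 to 3.09), by Fisher's exact test. Among lower regions they made up 8.65% in LT-HSC and 8.78% in MPP. Neighbouring regions are not independent, so these intervals are too narrow.

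The genotype effects in the 2 populations shared many regions. Of the called regions 2767 were higher in both, where 312 would fall together if the calls were independent, and 836 were lower in both, against 98.4. Opposite calls were made at 11 regions. Across regions, which are not independent replicates, the log2 fold changes had a Pearson r of 0.442 and a Spearman rho of 0.458. By number of lower regions Sorcs2 led in both populations, a count made after the values were seen, with 28 of its 64 regions in LT-HSC and 25 in MPP, while Adcy2 had 13 of 17 lower in MPP.

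**Figure D4:**
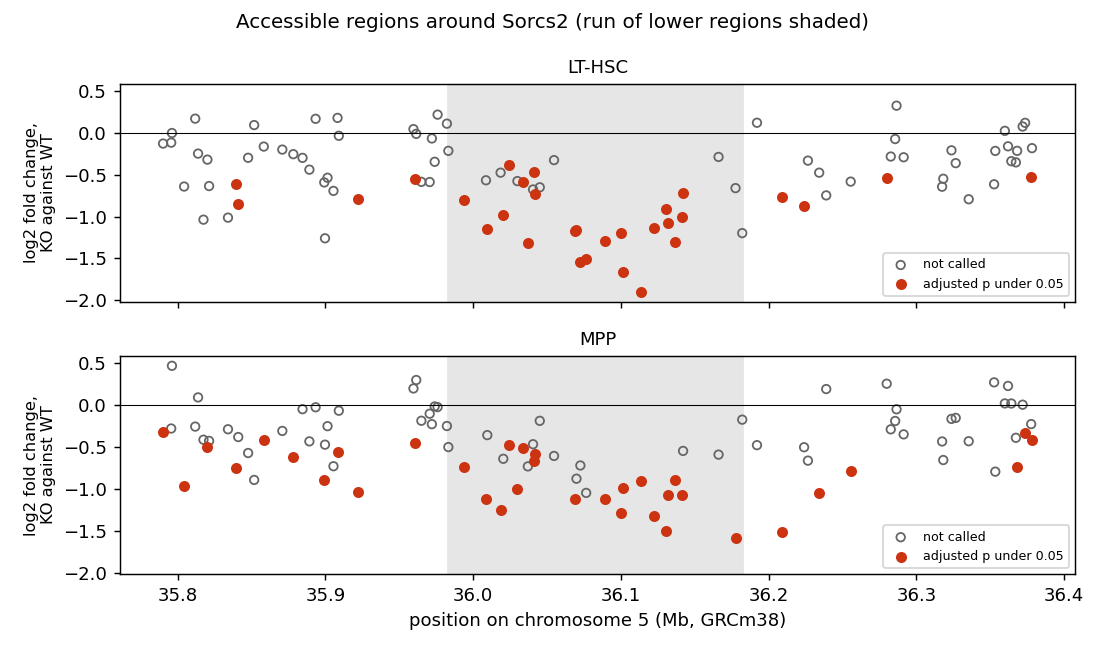
Each point is a region, placed by its chromosome 5 position and by its log2 fold change of KO against WT, in LT-HSC and in MPP, and filled where the adjusted p was under 0.05. The shaded run from 35982999 to 36182296 holds 32 regions, 22 called lower in LT-HSC and 19 in MPP.

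The interaction of genotype and population asked whether the effect of Phf6 loss differed between LT-HSC and MPP. A handful of regions passed, and none belonged to the chaperone or immediate early genes above. Camk1d, a calcium-dependent kinase gene (chromosome 2, start 5379111), held 37.1 CPM in WT and 35.5 CPM in KO LT-HSC, and 46.0 CPM in WT and 69.9 CPM in KO MPP (difference of log2 fold changes 0.66 ± 0.11, adjusted p = 0.0164). Gphn, the gephyrin gene (chromosome 12, start 78350782), held 46.5 and 37.7 CPM in WT and KO LT-HSC, and 66.8 and 84.9 CPM in WT and KO MPP (0.65 ± 0.09, adjusted p = 0.00227). Sspn, the sarcospan gene (0.70 ± 0.12), and Cntnap5b (0.65 ± 0.12) also passed. All 15 regions called had the more positive effect in MPP, and 3 remained without regions on Y, on unplaced scaffolds or above 100 CPM. With TMM scaling and all libraries edgeR called 0 regions in the other direction, where 14082 regions of either sign had an unadjusted p under 0.05. There edgeR called 3 with total counts, 6 with the loess offset, 6 with the gene-end covariate, 142 with replicate number as a block, and 1 each without a filter and on autosomes alone. It called 13, 1, 9 and 3 there without WT LT-HSC 3, WT MPP 1, WT MPP 3 and KO MPP 1. DESeq2 called 71, 38 of them positive and 33 negative, and limma-voom called 8. The lowest p among negative effects belonged to regions at Spsb1 (-0.59, adjusted p = 0.0574), Tifab (adjusted p = 0.0636) and Ptpn14 (-1.01, adjusted p = 0.0641). DESeq2 called all 3 (adjusted p = 0.0052, 0.0052 and 0.00825), and over their alternatives the adjusted p ran from 0.000694 to 0.3, from 0.0011 to 0.3 and from 0.00492 to 0.345. None of the 17 lists passed, and the lowest adjusted p was 0.0951, for ribosome biogenesis, which passed without WT MPP 3 (0.0425; range 0.0425 to 0.461).

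The interaction calls changed when 1 library was left out, in fits with fewer samples and so less power. The count was 2, 7 and 31 without WT LT-HSC 1, 2 and 3, 2 without KO LT-HSC 3, and 9 and 5 without KO MPP 2 and 3. Without KO LT-HSC 2 edgeR called 0 regions, with 13169 at an unadjusted p under 0.05, and no other tool was run on that subset. The Gphn call was lost there (adjusted p = 0.0553; range over its alternatives 5.22e-07 to 0.0553). The Camk1d call was lost without WT LT-HSC 1 (0.147), WT LT-HSC 2 (0.0661), KO LT-HSC 2 (0.175), KO LT-HSC 3 (0.135), KO MPP 2 (0.0544) and KO MPP 3 (0.126), in a range from 5.03e-06 to 0.175. The Sspn call was lost without WT LT-HSC 1 (0.172), WT MPP 1 (0.0666), WT MPP 2 (0.0525), KO LT-HSC 2 (0.188), KO LT-HSC 3 (0.16), KO MPP 1 (0.0794) and KO MPP 3 (0.159), in a range from 0.00041 to 0.188. The Cntnap5b call was lost without every library of LT-HSC except WT 3 and KO 1 and every library of MPP except WT 3 and KO 1 (0.0525 to 0.291, in a range from 0.000398 to 0.291).

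The comparison of MPP with LT-HSC in WT asked how the populations differ without the mutation. Regions at stem cell genes were lower in MPP, and regions at genes of lymphoid and myeloid progenitors were higher. A region of Slamf1, which encodes the stem cell surface marker CD150, fell from 15.9 ± 1.33 CPM in LT-HSC to 1.08 ± 0.0885 CPM in MPP (log2 fold change -3.86 ± 0.13, adjusted p = 1.43e-21), and Hlf, a stem cell transcription factor gene, fell from 16.9 ± 0.416 to 3.53 ± 0.183 CPM (-2.26 ± 0.10). The gene end of Mpo, the myeloperoxidase gene of granulocyte precursors, rose from 1.89 ± 0.32 to 11.99 ± 0.628 CPM (2.67 ± 0.12), and Ctsg, the cathepsin G gene, rose by 3.99 ± 0.16. Coq2, of coenzyme Q synthesis, was among the strongest gains, from 0.447 ± 0.0375 to 20.1 ± 2.87 CPM (5.48 ± 0.17), and a region at Stard4, of intracellular cholesterol transport, fell to 0.268 ± 0.0755 CPM (-5.44 ± 0.19).

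The lists followed these genes in WT. HSC identity had 84 of 710 regions higher and 468 lower in MPP, or 84 and 471 adjusted over the list alone (adjusted p = 1.61e-09). MPP and lymphoid priming had 118 of 193 higher and 31 lower, or 119 and 31 (adjusted p = 4.04e-06), with Satb1 (log2 fold change 3.68 ± 0.20) and Dntt (1.84 ± 0.09), genes of early lymphoid cells. Myeloid genes had 140 of 216 higher and 32 lower, or 142 and 33 (adjusted p = 1.69e-06). Cell cycle genes had 134 of 249 higher and 41 lower, adjusted over the list alone as over all regions (adjusted p = 0.000356), with Cdk6 (2.40 ± 0.09) and Mcm5 (2.82 ± 0.12). HSC aging genes had 75 of 270 higher and 134 lower, or 75 and 135 adjusted over the list alone (adjusted p = 0.0317), with Nupr1 (-3.51 ± 0.08) and Aldh1a1 (-3.27 ± 0.12). These 5 passed with an estimated correlation too (adjusted p = 0.00428, 0.00592, 0.00592, 0.0444 and 0.035 with an estimated correlation). Cell cycle missed on gene-end regions alone (0.217; range over its alternatives 0.000266 to 0.217) and HSC aging away from gene ends (0.0778; range 0.00513 to 0.0778).

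Further lists passed in WT with the preset correlation alone. Hoxa regions were lower in MPP, 33 of 54 against 3 higher (adjusted p = 0.000356, but adjusted p = 0.115 with an estimated correlation), as were megakaryocyte and erythroid regions, 73 of 134 against 25 (adjusted p = 0.00473, but adjusted p = 0.0738 with an estimated correlation). Vwf, the von Willebrand factor gene, fell by 3.75 ± 0.18 on the log2 scale. TNF and NF-kB regions were higher, 143 of 297 against 71 (adjusted p = 0.0222, but adjusted p = 0.104 with an estimated correlation), and so were ribosome biogenesis regions, 38 of 76 against 16 (adjusted p = 0.0377, but adjusted p = 0.0885 with an estimated correlation). Immediate early regions were higher at 140 of 319 against 80 (adjusted p = 0.0452, but adjusted p = 0.459 with an estimated correlation). Over the alternatives the adjusted p ran from 0.000186 to 0.115 for Hoxa, 0.00181 to 0.204 for megakaryocyte and erythroid, 0.0142 to 0.143 for TNF and NF-kB, 0.0199 to 0.206 for ribosome biogenesis and 0.0131 to 0.915 for immediate early genes. Adjusted over the list alone the counts were the same for these 5, except for 73 lower regions of TNF and NF-kB. The immediate early call was lost without WT LT-HSC 2 (0.160), WT MPP 1 (0.0768) and WT MPP 3 (0.0513), and the ribosome biogenesis call without WT MPP 1 (0.0541). The other 7 lists did not pass: B cell (0.0632), NuRD complex (0.067, and adjusted p = 0.0444 with an estimated correlation), interferon (0.221), Notch and T-ALL (0.509), NK cell (0.85), T cell (0.862) and macrophage and endothelial (0.862). In all, 130002 regions passed, 64488 higher and 65514 lower in MPP, and 33437 and 34707 by at least 2-fold. Libraries did not overlap at 70.5% of tested regions, against 10% given by chance.

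In KO the same comparison asked whether the populations still differ without Phf6. Stem cell regions were again lower in MPP, with Slamf1 (16.1 ± 0.763 to 1.66 ± 0.373 CPM, log2 fold change -3.24 ± 0.12) and Hlf (-2.37 ± 0.10). Mpo (3.01 ± 0.172 to 14.8 ± 1.51 CPM, 2.30 ± 0.12), Ctsg (4.47 ± 0.18) and Satb1 (3.48 ± 0.20) were higher. HSC identity had 77 of 710 regions higher and 471 lower, or 78 and 473 adjusted over the list alone (adjusted p = 1.36e-09). MPP and lymphoid priming had 119 of 193 higher and 33 lower (adjusted p = 2.94e-06), or 120 and 34 adjusted over the list alone, and myeloid genes had 137 of 216 higher and 26 lower, or 138 and 28 (adjusted p = 2.68e-07). Cell cycle (138 of 249 higher, 35 lower, adjusted p = 0.000117) and HSC aging (71 of 270 higher, 133 lower, adjusted p = 0.04) passed as well, with the same counts adjusted over the list alone. These 5 also passed with an estimated correlation (adjusted p = 0.00417, 0.00461, 0.00461, 0.0306 and 0.0306 with an estimated correlation). Cell cycle missed on gene-end regions alone (0.312; range over its alternatives 4.19e-05 to 0.312) and HSC aging away from gene ends (0.0844; range 0.0122 to 0.0844).

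Hoxa genes in KO had 29 of 54 regions lower and 3 higher in MPP (adjusted p = 0.00072, but adjusted p = 0.151 with an estimated correlation). Megakaryocyte and erythroid genes had 71 of 134 lower and 25 higher (adjusted p = 0.0132, but adjusted p = 0.0979 with an estimated correlation), and TNF and NF-kB genes had 147 of 297 higher and 64 lower (adjusted p = 0.00834, but adjusted p = 0.0926 with an estimated correlation). Adjusted over the list alone the counts were the same except for 73 lower megakaryocyte and erythroid and 66 lower TNF and NF-kB regions. Over the alternatives the adjusted p ran from 0.00028 to 0.151 for Hoxa, from 0.00673 to 0.258 for megakaryocyte and erythroid and from 0.00245 to 0.0926 for TNF and NF-kB. The other lists did not pass: NuRD complex (0.0604, and adjusted p = 0.0306 with an estimated correlation), B cell (0.0938), immediate early (0.149), ribosome biogenesis (0.214), interferon (0.245), T cell (0.735), Notch and T-ALL (0.735), macrophage and endothelial (0.88) and NK cell (0.959). In all, 126152 regions passed in KO, 62099 higher and 64053 lower in MPP. Of the regions called, 55184 were higher and 57425 lower in MPP in both genotypes, 43 were called in opposite directions, and the log2 fold changes had a Pearson r of 0.954 across regions.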

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

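The interaction test itself, which singled out the results here, was chosen before the data were examined, and so were the splits of the samples.

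The genotype effect differed between LT-HSC and MPP at 15 regions by the edgeR interaction test, each with the more positive effect in MPP. A region of Sspn had a difference of log2 fold changes of 0.6965, one of Camk1d 0.6609, one of Cntnap5b 0.6525 and one of Gphn 0.6492. Without KO LT-HSC 2 all 4 of these calls were lost, with adjusted p of 0.188, 0.175, 0.291 and 0.0553. That fit had fewer samples, so lost calls alone do not show that the effects depend on that library. Over all alternatives the adjusted p ran from 0.00041 to 0.188 for Sspn, 5.03e-06 to 0.175 for Camk1d, 0.000398 to 0.291 for Cntnap5b and 5.22e-07 to 0.0553 for Gphn. Chance is not excluded for the count of 15 by this count of splits: of 30 drawn of the 200 reassignments of genotype within each population, 3 gave at least as many, the real one included. The highest other gave 2456 regions and kept WT and KO MPP apart, and the next gave 120 and kept WT and KO LT-HSC apart. Each so carries the genotype effect of 1 population into its interaction, which points to a structure of the samples. Of the 2 drawn splits that kept WT and KO LT-HSC apart, the other gave 0 by edgeR, so that effect alone did not set the count. In a count made after the result was seen, 0 of the 26 that mixed the genotypes in both populations gave as many by edgeR, and the highest gave 5. Mixing puts the genotype effect into the spread within groups, which can hold such counts down, so they do not exclude chance for the 15.

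For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each of the 4 comparisons 1 split, the real one, gave its count. The real counts and the highest of the other splits were 8834 and 10 for KO against WT in LT-HSC and 16230 and 12 in MPP. For MPP against LT-HSC edgeR called 130002 in WT and 126152 in KO, and the highest of the other splits was 0 in both. The other splits mix the groups, which widens the spread within them and can hold their counts down. These counts therefore do not exclude chance.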

How the results depend on the processing

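Alternatives added after the data were examined were the gene-end share as a covariate, regions away from gene ends, without repeat-like regions, and without WT library 2 of both populations. Across all alternatives 7187 values of named regions stayed on their side of the threshold, 391 lost the call, 41 gained it and 0 reversed with a call in either fit. A change of sign with no call in either fit counted as kept, for regions and for lists. Region values with no adjusted p were left out. Of list values 1216 were kept, 49 lost and 26 gained the call, and 1 reversed: immediate early genes in MPP against LT-HSC in WT on gene-end regions alone (-0.0484). Of the counts per comparison 80 stayed within 1.5 times and 30 moved. At an adjusted p under 0.01 there were 2418 regions in LT-HSC, 5406 in MPP and 5 for the interaction, as that threshold must lower counts. The gene-end covariate gave 1843 in LT-HSC, 5614 in MPP, 24 for the interaction and 86109 for MPP against LT-HSC in WT. It took 1 residual degree of freedom. The share is computed from these same counts. Its ranges did not overlap between WT and KO LT-HSC, nor between the populations within a genotype. The covariate can thus take up the group differences themselves, so calls that it ended do not by themselves show a weak effect. The cause of the lower counts was not otherwise tested. Without WT library 2 of both populations MPP gave 10653. The interaction gave 71 with DESeq2, 27 with total counts, 32 with the loess offset, 8 with limma-voom, 3 without repeat-like regions and 4 away from gene ends, and the cause was not tested.

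Leaving out 1 library gave 3404 to 6586 regions in LT-HSC, 6435 to 14169 in MPP and 0 to 31 for the interaction by edgeR, with fewer samples. The block by replicate number tied LT-HSC and MPP of equal number within a genotype for the interaction and for MPP against LT-HSC. For KO against WT it tied WT and KO of equal number within a population. With the block the interaction rose to 233, 91 of them positive and 142 negative, including all 15. KO against WT then gave 9204 in LT-HSC and 16316 in MPP. The labels do not pair the libraries. After removal of group means, log2 CPM of LT-HSC and MPP of the same number and genotype were correlated across regions. The r was 0.073, 0.089 and 0.114 in WT and 0.054, 0.064 and 0.055 in KO. Each was above the pairings of LT-HSC with MPP of unlike number in that genotype, at most -0.006. WT and KO libraries of the same number had r from -0.037 to 0.033, so across genotypes they shared only a number. WT and KO libraries of unlike number reached 0.066 in LT-HSC and 0.058 in MPP, as high as the values within KO, so r of this size does not show a shared animal. With the block of WT and KO by number, which is no pairing by animal, the T cell list passed in KO against WT in MPP (adjusted p = 0.046, range over its alternatives apart from fry 0.046 to 0.317). For MPP against LT-HSC in WT the block ended the calls of the immediate early (adjusted p = 0.0593) and ribosome biogenesis (0.0502) lists. In MPP against LT-HSC interferon passed away from gene ends in WT (0.0173; range 0.0173 to 0.959) and KO (0.0301; range 0.0301 to 0.958), and with tighter assignment B cell passed in WT (0.0418; range 0.0418 to 0.217) and the NuRD complex in KO (0.0463; range 0.0306 to 0.258). The test fry, which does not set a list against other regions, called 4 further lists in KO MPP, 4 in MPP against LT-HSC in WT and 7 in KO. The planned motif sets, GC offset, and block with GC offset were not run for want of a genome. In simulated data, with far fewer changed regions than were called here, 1.5-fold changes were recovered at 26.9% in LT-HSC and 17.9% in MPP.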

Other observations

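Tests written after the result was seen were the spread of heat shock and immediate early regions within WT and the spread of fold changes within runs of lower regions, whose chi-square was chosen last, with its values known. So were the sets of regions lower in both populations, and the heat shock list and the counts per gene were also chosen after the data were examined.

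Several genes held many called regions, a ranking by count that was not tested for enrichment and favours genes with many regions. Of the regions assigned to Klf6, 12 of 29 were higher in KO LT-HSC, as were 11 of 37 at Fos, 9 of 40 at Jmjd1c, a histone demethylase family gene, and 7 of 20 at Ski, a repressor of TGF-beta signalling. In KO MPP 21 of 166 regions were higher at Pde4d, a cAMP phosphodiesterase gene, 13 of 56 at Zeb2, a transcription factor of haematopoietic differentiation, 12 of 103 at Mecom, 10 of 26 at Hgf, the hepatocyte growth factor gene, and 9 of 78 at Angpt1, the TIE2 ligand. By count the lower regions of LT-HSC were led by Sorcs2 (28 of 64) and Sfi1 (16 of 38), a centrosome gene. In MPP lower regions lay at Sorcs2 (25 of 64), Adcy2, an adenylyl cyclase gene (13 of 17), Gli2, a Hedgehog effector (10 of 37), and Nrxn3, a synaptic adhesion gene (9 of 43). A list of 25 heat shock genes, 23 of them with a total of 169 regions, had 49 higher regions in KO LT-HSC at 18 genes and 53 higher and 2 lower in KO MPP, with higher regions at 19 genes.

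Heat shock and immediate early regions were higher in KO in both populations, with medians over all 488 regions of both lists of 0.182 in LT-HSC and 0.186 in MPP on the log2 scale. A general gain of strong regions and gene ends was smaller in matched regions: of 10000 random sets matched on place and level the highest medians were 0.0808 and 0.0708. The heat shock list was chosen after the data were examined, and the sets ignore that regions of 1 gene can move together. These sets therefore do not exclude that explanation. The immediate early list, chosen before, had medians of 0.184 and 0.164 but was not set against matched sets by itself. Handling that differed between preparations is a candidate explanation: within WT the SD of the 148 called regions was 2.08 times that of matched sets in LT-HSC and 1.85 times in MPP, above all 10000 sets, and within KO it was 0.116 against 0.0950 and 0.123 against 0.0957, above 95% of sets, although these regions were lower in WT than their matches, which alone could raise the SD of log2 values. WT library 2 was lowest in both populations (heat shock regions at -0.90 and -0.81 from the population mean, other WT libraries from -0.48 to -0.18), but without it 92 of the 148 regions were still called in each population, against 118 and 110 with it, and their median log2 fold change was 0.466 and 0.457 in place of 0.556 and 0.546. An effect of Phf6 loss and one of Cre-ERT2, present in KO alone, stay open and untested.

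Runs of neighbouring lower regions lay at Sorcs2 (32 regions over 199 kb, 22 called lower in LT-HSC and 19 in MPP) and at Adcy2 (22 regions over 653 kb, 3 and 14 called). Loss of a DNA copy over a whole run would give its regions 1 fold change, and is argued against as the whole cause, since the chi-square per degree of freedom about the run's mean was 5.83 and 2.42 at Sorcs2 and 2.66 and 3.75 at Adcy2, in LT-HSC and MPP (highest p = 5.29e-05), against at most 1.32 in the 9 other splits of each population, whose mixed genotypes can widen the SE. The regions more than 2 SE from that mean were 28.1% and 21.9% at Sorcs2 and 18.2% and 22.7% at Adcy2. Noise alone would leave about 5%, but only the first met the bound of 25% set before the chi-square bound was chosen. A loss over part of a run was not tested. Weighted means of the runs were -0.92 and -0.851 at Sorcs2 and -0.562 and -1.03 at Adcy2, in LT-HSC and MPP. Except at Adcy2 in LT-HSC these were near the 2-fold fall that loss of 1 of 2 copies would give. There the size of the fall does not argue against a lost copy. A shift of cell types between LT-HSC and MPP within the sort gates would lower regions of like level and like population difference alike. The run medians were -0.945 and -0.805 at Sorcs2 in LT-HSC and MPP, and -1.068 at Adcy2 in MPP. They lay below all 10000 sets matched on level and on the difference between the populations (lowest -0.342, -0.308 and -0.377). They also lay below all such sets of regions lower in both (-0.492, -0.577 and -0.568). At Adcy2 in LT-HSC the median of -0.489 lay below the former (-0.364) and not the latter (-0.579), so picking by sign could account for it. The runs were picked for their many lower regions and the sets were drawn region by region, so low ranks were likely from the start. The sets show that typical matched regions fell less, but they do not exclude the shift, which stays open at both genes. Other cell types in the gates, a strain difference between the mouse lines, untested because it needs reads, and an effect of Phf6 may each underlie the runs.

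Gene ends were over-represented among regions higher in KO. More signal over background in KO libraries would raise all regions of like level, and is argued against only as the whole cause, since the median log2 fold change of gene ends was 0.061 in LT-HSC and 0.061 in MPP, above all 1000 matched sets of other regions (highest 0.0458 and 0.0136). The median of those sets was 0.0408 in LT-HSC and 0.00651 in MPP, so in LT-HSC most of the gain was shared by other regions of like level. With the loess offset, which allows for region strength, the odds ratio was 2.52 in LT-HSC (2.33 to 2.72) and 2.47 in MPP (2.35 to 2.60). These ratios were not matched on level, and stronger regions can pass the test more readily. They therefore do not decide whether scaling that ignores region strength caused the over-representation, and that explanation stays open. GC content was not tested for want of a genome, and a preference of the Phf6 effect for gene ends could also account for it.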
